A study of Homo sapiens with 60 samples.

How the data were processed

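RNA of HepG2 cells was sequenced by the authors on an MGI instrument with paired 100 bp reads after directional library preparation, from RNA with an integrity number above 7. The libraries of the ethanol extracts of 8 preparations and of the vehicle were used. Other libraries in the same table, with water extracts or wortmannin, were left out, so that 60 of 270 columns were used and 210 were not. The deposited values are expected counts per Ensembl gene. They fit the RSEM output named in the authors' notes, since they are not negative, 8.21% of them are not whole numbers (tolerance 1e-09) and the column totals differ. The notes list FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 with the GRCh38 genome and do not state the annotation release. Symbols, types and positions were therefore taken from GENCODE 29 and a gene symbol table, which matched 41209 of 60675 identifiers holding 99.41% of the counts, and 19466 identifiers had no symbol.

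Groups were defined by extract and dose as the sample titles give them. The titles of all libraries carry the same batch label, BatchD. Libraries also carry a code prefix shared by 2 extracts, and the vehicle has its own prefix. Comparisons with vehicle, with the other extracts at 20 µg/mL and of Angelica with Cnidium therefore cross prefixes. Replicate numbers were treated as labels without pairing, because the labels do not say what a number shares. The mean residual correlation of libraries of equal number was 0.004 between vehicle and extracts (54 pairs). Within a code prefix it was 0.053 for equal numbers (126 pairs) and −0.031 for other numbers (216 pairs). Residuals were taken from each group's own mean, which ties these values to each other, so the negative one is no separate observation. The pairs are also not independent. Libraries of equal number may share something within a prefix, and blocks by number were fitted as alternatives. Library depth ran from 21485865 to 34643018 summed expected counts. Between replicates the chi-square per degree of freedom ran from 2.81 to 63.2 over 48 pairs, above the value of 1 for counting error alone. It is a mean over genes with a summed count of at least 20, in which abundant genes weigh most. Replicates thus varied beyond counting error, but the value does not tell how far depth limits genes with low counts. No pair of columns was identical.

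Expected counts were rounded to whole numbers, filtered with filterByExpr on the 25 groups (16692 genes tested) and scaled by TMM (factors 0.78 to 1.1) in edgeR 4.0.16 under R 4.3.3. One quasi-likelihood model of all 60 libraries, with 35 residual degrees of freedom, gave each contrast, which assumes a common spread for groups of 1, 2 and 3 libraries. The common coefficient of biological variation was 0.06. Samul-tang was fitted apart, with its 3 doses as a group against vehicle (14803 genes tested). Tests were two-sided, p was adjusted by Benjamini-Hochberg within each contrast, and genes with an adjusted p below 0.05 were called. Contrasts were each dose against vehicle, 500 against 20 µg/mL within each extract, and at 500 µg/mL Angelica against Paeonia, Cnidium against Rehmannia, Astragalus against Cinnamon and Angelica against Cnidium.

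Of 34 fixed gene lists 32 had at least 3 tested genes and were tested by camera in limma 3.58.1 with a preset correlation of 0.01, with p adjusted over lists. A list was also tested with its own estimated correlation and with fry, which asks only whether its members move 1 way on balance. Counts of called members are given over all genes and adjusted over the list alone. Named genes at 500 µg/mL against vehicle were the 6 largest rises and the 6 largest falls among genes with a symbol, an adjusted p below 0.05, a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups. Up to 3 members each of up to 4 lists with the smallest p were added, with a panel of 8 genes, among them CYP1A1, NQO1, HMOX1, CYP3A4, ASNS, CDKN1A and ALB. The remaining panel gene and 2 other genes are not reported here. For the lower doses the 3 largest and for the other contrasts the 5 largest in each direction were taken, and members of fixed lists were used as examples. Differences between extracts were collected for the closing section from the counts and 7 of the panel genes. Similarity was the Pearson correlation across genes of the changes from 20 to 500 µg/mL. CPM are counts scaled to a common library size by the TMM factors. Principal components used log2 CPM with a prior count of 2.

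The groups, contrasts, lists, naming rule and the alternatives were set before the data were examined, except for 3 alternatives. These were the mean of the other 6 extracts' 20 µg/mL groups as reference for the 100 and 20 µg/mL counts, planned only for 500 µg/mL, an offset for the trend of each library on GC content and transcript length, and each Cinnamon library at 100 µg/mL left out alone, run because replicate 1 stood apart. Replicates were also left out under the first of these only after its counts were seen. The alternatives set beforehand were RLE factors, no filter on low counts, DESeq2 1.42.0, a fit of the 2 groups compared, replicate number as a block, replicate number within code prefix as a block, a fold of at least 2, the other list tests, Spearman correlation or called genes for similarity, and each replicate left out. Leaving out an extract replicate removed that number from all extract groups of more than 1 library at once. Counts without an extract replicate therefore also reflect a fit with fewer libraries. Most libraries were lost without replicate 2, the only number found in every replicated extract.

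On simulated data with the fitted spread the model recovered 84% of genes changed 1.5-fold and 94% of those changed 2-fold for Cnidium at 500 µg/mL against vehicle, and 80% and 90% for Angelica, with 2 libraries. For Angelica at 500 against 20 µg/mL it recovered 78% and 86%. False calls numbered 6 to 11 per simulated contrast of this model, 14 in the separate Samul-tang fit and 5 by DESeq2. Changes were placed only in genes with an expected count of at least 20 in a library of median size, and each gene was drawn independently. These figures thus do not cover changes in genes with lower counts, or shifts of a library across many genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.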

Results

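Gene expression was measured by RNA sequencing in HepG2 cells, a human hepatocellular carcinoma line, exposed for 24 h to 70% ethanol extracts of tonifying herbal medicines or to vehicle. The extracts came from 6 single drugs and 2 formulas. The drugs were Angelicae Gigantis Radix, Paeoniae Radix, Cnidii Rhizoma, Rehmanniae Radix Preparata, Astragali Radix and Cinnamomi Cortex, called Angelica, Paeonia, Cnidium, Rehmannia, Astragalus and Cinnamon here, and the formulas were Sagunja-tang and Samul-tang. Each extract was given at 500, 100 and 20 µg/mL. The 60 libraries formed 25 groups. There were 3 vehicle libraries, 3 per dose for Cnidium, Rehmannia, Astragalus and Cinnamon, 2 per dose for Angelica, Paeonia and Sagunja-tang, and 1 per dose for Samul-tang. The summed expected counts per library ran from 21485865 to 34643018, and those of the vehicle libraries from 26383858 to 31017837. Labels of the vehicle give 0.1% DMSO whereas the series text gives 2%, and the counts cannot settle which was used. The 2 sources also differ on dose, since the series text describes a lower dose series for extracts with a 20% inhibitory concentration below 500 µg/mL and all labels give the same 3 doses. Values below are log2 fold changes ± SE from the fit of all groups, with n given as extract against reference libraries, and a gene is said to have risen or fallen where its adjusted p lay below 0.05.

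The libraries of Astragalus at 500 µg/mL lay farthest from the rest along the first principal component, which held 30.5% of the variance, and those of Astragalus at 100 and Paeonia at 500 µg/mL lay between. The second component held 5.4% and set the vehicle libraries, at 19.7 to 27.3, apart from nearly all extract libraries. Cinnamon replicate 1 at 100 µg/mL was an exception at 25.9, while the other Cinnamon libraries of that dose lay at 0.2 and 0.3. Transcripts of the mitochondrial genome took 14.2% ± 0.93 (SD, n = 3) of the counts in vehicle, 25.8% ± 1.45 (n = 3) in Astragalus and 20.9% ± 1.7 (n = 2) in Paeonia at 500 µg/mL, and group means of the other replicated groups ran from 14.45% to 19.82%.

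**Figure D1:**
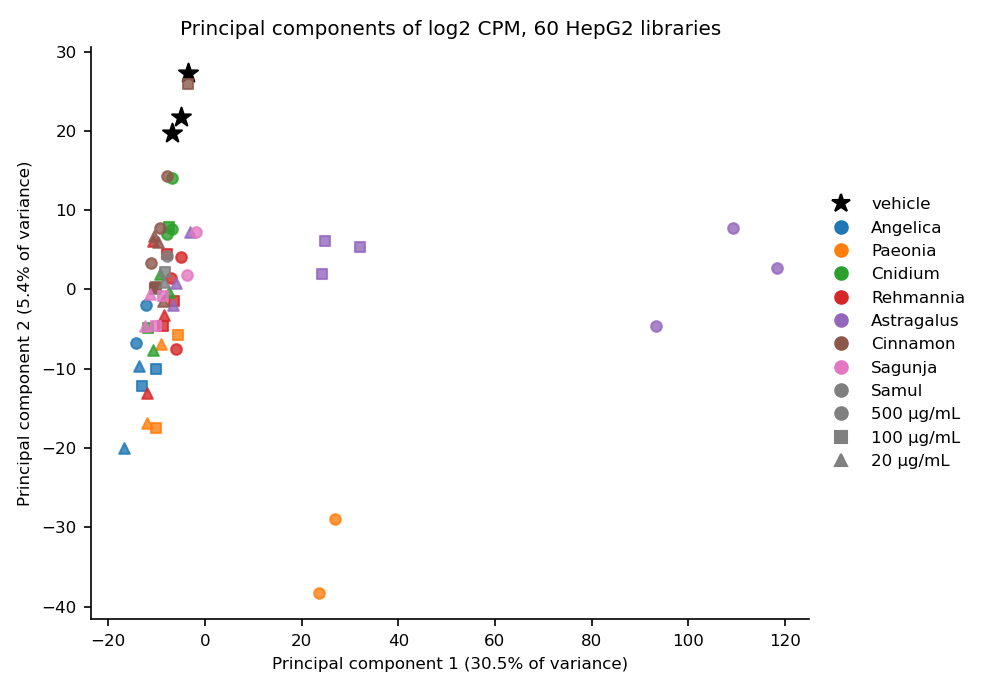
Each point is a library, coloured by extract and shaped by dose, with its scores on principal component 1 (horizontal, 30.5% of the variance) and 2 (vertical, 5.4%) of log2 CPM. Astragalus at 500 µg/mL lies apart along the horizontal axis, and the 3 vehicle libraries lie at 19.7 to 27.3 on the second.

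A set of genes separated vehicle from all extracts irrespective of dose. PFKFB3, whose product makes the fructose 2,6-bisphosphate that stimulates glycolysis, rose in all 7 replicated extracts at all 3 doses, by 1.09 to 3.14. Its identifier is ENSG00000170525, and it lies on chromosome 10 from 6144934 to 6254644. TMCC1, which encodes a protein of the endoplasmic reticulum membrane, also rose in each of these 21 comparisons, by 1.03 to 2.57. At 20 µg/mL CA9, a carbonic anhydrase induced by hypoxia, rose by 0.67 to 1.37 in the 7 extracts. RN7SL1, the RNA of the signal recognition particle, fell in all 7 at that dose, for example by 2.14 ± 0.35 in Angelica (n = 2 against 3) and by 1.22 ± 0.27 in Astragalus (n = 3 against 3). Its call ended in Paeonia without extract replicate 2 (−1.47) and in Rehmannia without vehicle replicate 2 (−0.82), with an adjusted p of 0.059 and 0.060, the highest over the alternatives of each. HSPA8 and HSPA1A, heat shock chaperones, rose by 0.58 to 0.72 and by 0.98 to 1.12 at 20 µg/mL.

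Taking the 20 µg/mL groups of the 7 extracts as a mean against vehicle, 14 of 19 hypoxia targets rose (adjusted p = 3.2e-13, and adjusted p = 0.024 with an estimated correlation), as did 8 of 15 heat shock genes (3.3e-11 and 0.00088) and 13 of 18 endoplasmic reticulum chaperones (3.5e-07 and 3.1e-05). Of the 23 genes for DNA replication 16 fell, with an adjusted p of 5.8e-08 and an adjusted p = 0.084 with an estimated correlation. In the same contrast 20 of 34 nuclear genes for oxidative phosphorylation subunits fell (7.1e-05, and adjusted p = 0.35 with an estimated correlation), 7 of 17 glycolysis genes rose (0.0039 and 0.27) and 6 of 13 mitochondrially encoded genes rose (0.015 and 0.54). By edgeR 449 genes were higher and 329 lower than vehicle at 20 µg/mL in all 7 extracts at once. For that reason each extract was also compared with the mean of the 20 µg/mL groups of the other 6 replicated extracts, and from 20 to 500 µg/mL within itself, neither of which uses a vehicle library. Changes against vehicle given below, above all at the lower doses, may include this shared part.

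**Figure D2:**
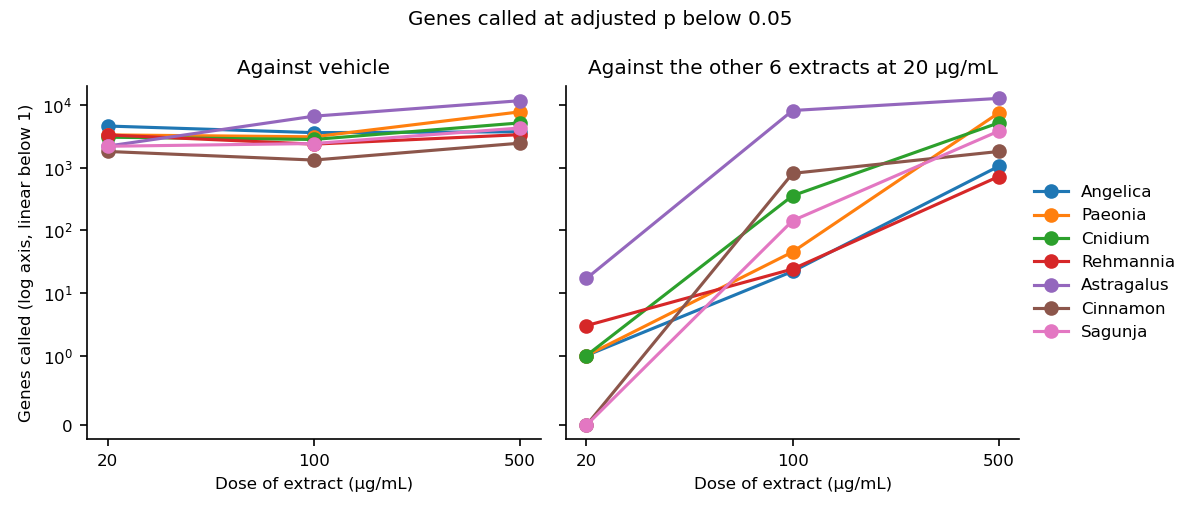
Points joined by lines give the number of genes called at an adjusted p below 0.05 (log axis, linear below 1) by dose of extract in µg/mL, against vehicle on the left and against the 20 µg/mL groups of the other 6 replicated extracts on the right. At 20 µg/mL the counts against vehicle run from 1805 to 4594, and those against the other extracts run from 0 to 17.

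At 500 µg/mL Angelica raised CYP1A1, a monooxygenase that the aryl hydrocarbon receptor (AhR) induces, by 3.03 ± 0.11 (n = 2 against 3), which is 8.19-fold. CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610 in GRCh38) stood at 11.7 ± 0.113 CPM, the count scaled by library size, in vehicle (SD, n = 3). Genes of cholesterol synthesis fell, among them HMGCS1 by 0.54 ± 0.06, LSS by 0.63 ± 0.07 and TM7SF2 by 0.63 ± 0.06. The aldo-keto reductases AKR1B10 (1.09 ± 0.08), AKR1C2 (0.94 ± 0.07) and AKR1C1 (0.70 ± 0.07), targets of the oxidative stress regulator NRF2, rose. ACOT1, a cytosolic acyl-CoA thioesterase, fell by 1.06 ± 0.15.

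In the fixed lists 18 of 23 cholesterol synthesis genes fell, 20 when adjusted over the list alone (adjusted p = 5.3e-23). Of 25 NRF2 targets 17 rose, 18 adjusted over the list alone (9.8e-19). Hypoxia targets rose in 14 of 19 (4.2e-13) and heat shock genes in 9 of 15, 11 adjusted over the list alone (1.2e-11), and both groups had moved the same way at 20 µg/mL against vehicle. Fatty acid synthesis genes fell in 11 of 14 and AhR targets rose in 4 of 8, the same numbers as when adjusted over the list alone (1.9e-11 and 2.0e-11). All 13 mitochondrially encoded genes rose (9.4e-08), with an adjusted p = 0.22 with an estimated correlation, as mitochondrial transcripts took 19.7% ± 1.01 of counts. Their share was much the same at 20 µg/mL of Angelica, at 19.8% ± 2.96. The test of all genes called 3719 (1898 higher, 1821 lower), and 914 without extract replicate 2 or 1808 without extract replicate 3. With the other extracts at 20 µg/mL as reference it called 1047, and 77 or 510 without extract replicate 2 or 3, and 641 of the 1047 were also called against vehicle in the same direction.

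From 20 to 500 µg/mL Angelica raised CYP1A1 by a further 1.45 ± 0.11 (n = 2 against 2), AKR1B10 by 1.41 ± 0.09, AKR1C2 by 1.12 ± 0.08 and CPLX2, a regulator of vesicle fusion, by 0.82 ± 0.08. NRF2 targets rose in 16 of 25, 19 adjusted over the list alone (4.3e-60), and AhR targets in 2 of 8, 5 adjusted over the list alone (4.5e-14). Cholesterol synthesis genes fell in 11 of 23 and fatty acid synthesis genes in 7 of 14, 20 and 13 adjusted over the list alone (7.2e-33 and 2.1e-30). The gluconeogenic enzyme G6PC1 (−0.58 ± 0.14) and DEPP1 (−0.96 ± 0.20), a FOXO target, were among the 5 largest falls, whose adjusted p without extract replicate 2 or 3 ran from 0.11 to 0.77. The test called 176 genes (74 higher, 102 lower), and 9 without extract replicate 2 or 24 without extract replicate 3.

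The lower doses of Angelica already raised CYP1A1 against vehicle, by 2.21 ± 0.11 at 100 µg/mL and 1.58 ± 0.12 at 20 µg/mL (n = 2 against 3 each). At 100 µg/mL PFKFB3 rose by 2.42 ± 0.23 and RN7SL1 fell by 2.37 ± 0.37. AKR1B10 fell at 20 µg/mL (−0.32). The tests called 3603 genes at 100 µg/mL (1791 higher, 1812 lower) and 4594 at 20 µg/mL (2288 higher, 2306 lower). The first count was 849 without extract replicate 2 and 1062 without extract replicate 3, and the second 2572 and 1243. With the other extracts at 20 µg/mL as reference 22 genes were called at 100 µg/mL, and 2 or 1 without extract replicate 2 or 3. For 20 µg/mL 1 was called, CYP1A1 (1.71 ± 0.09, adjusted p = 1.1e-18), and 1 without either replicate.

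Paeonia at 500 µg/mL raised the insulin-like growth factor binding proteins IGFBP3 by 4.51 ± 0.20 and IGFBP1 by 4.08 ± 0.20 (n = 2 against 3). IGFBP1 (ENSG00000146678, chromosome 7, 45888357 to 45893668) went from 118.3 ± 12.1 to 2006 ± 107 CPM (SD). The cystine transporter SLC7A11 rose by 2.20 ± 0.08. HAMP, which encodes the iron hormone hepcidin (ENSG00000105697, chromosome 19, 35280716 to 35285143), fell by 4.13 ± 0.25. The metallothioneins MT1G (−2.72 ± 0.22) and MT1F (−2.56 ± 0.19) and the glutathione transferase GSTA1 (−2.04 ± 0.11) fell too, with reads of close paralogs in both families not fully separable.

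Hypoxia targets rose in 18 of 19 (adjusted p = 6.4e-28), with SLC2A1 at 1.41 ± 0.07 and LOX at 2.02 ± 0.12. All 14 immediate early genes rose (2.1e-19), such as EGR1 by 2.31 ± 0.10 and IER3 by 1.61 ± 0.07. Of 30 ATF4 targets, the genes of the integrated stress response, 20 rose (5.5e-16), with ASNS at 1.33 ± 0.06 and GDF15 at 1.93 ± 0.09. Glycolysis genes rose in 15 of 17 (9.7e-13), FOXO targets in 9 of 14 (1.7e-08), autophagy and lysosome genes in 15 of 22 (4.9e-08), NF-kappaB targets in 7 of 10 (2.5e-06) and gluconeogenesis genes in 7 of 9 (2.6e-06). Adjusted over the list alone these counts were the same except for FOXO targets, with 10. Genes for DNA replication fell in 21 of 23, 22 adjusted over the list alone (6.8e-18), with UHRF1 at −1.14 ± 0.07, and all 22 mitosis genes fell (4.6e-11).

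Cholesterol synthesis genes rose in 16 of 23 with Paeonia (3.3e-07), although HMGCS1 stood at −0.03 ± 0.05. Of 25 NRF2 targets 17 rose and 3 fell, among them ABCC3 and CBR1 (1.0e-05, and adjusted p = 0.056 with an estimated correlation). Metallothioneins fell in 6 of 9 (8.8e-05, and adjusted p = 0.065 with an estimated correlation). The test called 7739 genes (3897 higher, 3842 lower). Set against the other extracts at 20 µg/mL it called 7439, and 4622 without extract replicate 2, and 5782 were called against both in the same direction.

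Within Paeonia the step from 20 to 500 µg/mL raised IGFBP3 by 3.56 ± 0.22, the cytokine IL11 by 3.10 ± 0.24 and CYP1A1 by 2.41 ± 0.13 (n = 2 against 2). MT1G (−2.95 ± 0.23), MUC15 (−2.02 ± 0.16), the fatty acid hydroxylase CYP4V2 (−1.70 ± 0.15) and GSTA2 (−1.67 ± 0.14) fell. Immediate early genes rose in 13 of 14, 14 adjusted over the list alone (1.3e-27), ATF4 targets in 21 of 30, 23 adjusted over the list alone (3.1e-18), hypoxia targets in 17 of 19 (1.9e-17) and NRF2 targets in 20 of 25 (9.2e-14). Cholesterol synthesis genes rose in 17 of 23 (1.2e-12), all 22 mitosis genes fell (1.5e-16) and metallothioneins fell in 7 of 9 (5.5e-09), and all calls of these lists held with an estimated correlation. The test called 5108 genes (2796 higher, 2312 lower), and 2339 without extract replicate 2 or 2698 without extract replicate 3.

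At 100 and 20 µg/mL Paeonia lowered HAMP against vehicle (n = 2 against 3 each), with a change of −1.60 ± 0.18 at 20 µg/mL, and IGFBP1 rose by 1.31 ± 0.19 at 20 µg/mL. IGFBP1 also lay above the vehicle libraries in all libraries of the other extracts at 20 µg/mL, so its rise may include the part shared by all extracts. The amino acid synthesis gene ASNS rose at 100 µg/mL (0.44 ± 0.06). CYP1A1 stood at 0.15 and −0.16, neither called. The tests called 3092 genes at 100 µg/mL (1518 higher, 1574 lower) and 3317 at 20 µg/mL (1629 higher, 1688 lower). Without extract replicate 2 these counts were 173 and 114, and without vehicle replicate 2 they were 1828 and 2121. When set against the other extracts at 20 µg/mL, 45 genes were called at 100 µg/mL, but 0 or 6 by edgeR without extract replicate 2 or 3. The lowest dose called 1, HAMP (−0.96 ± 0.16, adjusted p = 0.0078), and 0 without either replicate.

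Cnidium at 500 µg/mL raised AKR1B10 (ENSG00000198074, chromosome 7, 134527592 to 134541408), an aldo-keto reductase, by 3.06 ± 0.07 (n = 3 against 3), from 41.3 ± 1.48 to 345.4 ± 13.4 CPM (SD). AKR1C2 rose by 2.42 ± 0.07 and AKR1C1 by 2.33 ± 0.07, although reads of these near-identical genes are hard to assign. PTGR1, which reduces prostaglandins and reactive aldehydes, rose by 2.33 ± 0.06, and GCLM, a subunit of the enzyme that starts glutathione synthesis, by 1.90 ± 0.07. GREB1L (−1.80 ± 0.13), the pro-apoptotic BMF (−1.55 ± 0.09) and the YAP target ANKRD1 (−1.45 ± 0.10) fell.

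NRF2 targets rose in 24 of 25 with Cnidium (adjusted p = 1.3e-142, and adjusted p = 9.6e-14 with an estimated correlation), including NQO1 at 1.17 ± 0.06 and HMOX1, heme oxygenase, at 0.78 ± 0.06. Of the cholesterol synthesis genes 22 of 23 fell (1.4e-33), with HMGCS1 at −0.87 ± 0.05 and FDFT1 at −0.60 ± 0.04, and fatty acid synthesis genes in 13 of 14 (3.2e-18), with ACSS2 at −0.92 ± 0.05 and SREBF1, their transcription factor, at −0.66 ± 0.06. Heat shock genes rose in 13 of 15 (1.5e-16) and endoplasmic reticulum chaperones in 12 of 18 (1.1e-05), lists that had also risen at 20 µg/mL. YAP and TGF-beta targets fell in 9 of 13 (2.2e-07). Adjusted over the list alone these counts were unchanged. The PXR and CAR targets were called higher (0.031, and adjusted p = 0.10 with an estimated correlation) with 4 risen and 2 fallen, a mean of 0.03 and a median of −0.06.

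CYP1A1 stood at 0.15 ± 0.11 in Cnidium at 500 µg/mL and was not called. The test called 5153 genes (2641 higher, 2512 lower, and 106 and 251 at a fold of at least 2), and 3023 without extract replicate 2. Relative to the other extracts at 20 µg/mL it called 5170, and 2808 without extract replicate 2, with 2801 genes called against both in the same direction.

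The step from 20 to 500 µg/mL of Cnidium raised AKR1B10 by 3.20 ± 0.07, the inositol transporter SLC5A11 by 2.56 ± 0.20 and PTGR1 by 2.37 ± 0.06 (n = 3 against 3). G6PC1, which releases glucose from its phosphate, fell by 1.33 ± 0.12 and BMF by 1.32 ± 0.09. Of the NRF2 targets 24 of 25 rose (1.2e-201). Cholesterol synthesis genes fell in 22 of 23 and fatty acid synthesis genes in 12 of 14, 23 and 14 adjusted over the list alone (7.2e-42 and 1.0e-27). Metallothioneins fell in 8 of 9 (9.0e-08) and genes of proteins that hepatocytes secrete in 13 of 20, 14 adjusted over the list alone (4.5e-06), and all these calls held with an estimated correlation. Heat shock genes rose in 9 of 15, 11 adjusted over the list alone (0.00058, and adjusted p = 0.054 with an estimated correlation). The test called 3069 genes (1595 higher, 1474 lower, and 57 and 101 at a fold of at least 2), and 1318 without extract replicate 2 or 1835 without extract replicate 3.

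At the lower doses of Cnidium AKR1B10 rose at 100 µg/mL (0.83) and was not called at 20 µg/mL (−0.14), while CYP1A1 fell by 0.36 ± 0.12 and 0.39 ± 0.12 against vehicle (n = 3 against 3). NQO1 rose by 0.27 ± 0.06 at 100 µg/mL. The sulfatase gene ARSI fell by 0.91 ± 0.10 at that dose. The tests called 2806 genes at 100 µg/mL (1430 higher, 1376 lower) and 3047 at 20 µg/mL (1515 higher, 1532 lower). Without extract replicate 2 they called 832 and 1511, and without vehicle replicate 2 they called 1595 and 1735. Relative to the other extracts at 20 µg/mL 355 genes were called at 100 µg/mL, and 32 or 62 without extract replicate 2 or 3. At 20 µg/mL 1 was called, CYP1A1 (−0.60 ± 0.10, adjusted p = 0.0025), with 4, 0 and 0 by edgeR without extract replicate 1, 2 and 3. Part of that difference comes from the reference, which includes Angelica, where CYP1A1 had risen by 1.58 against vehicle.

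In Rehmannia at 500 µg/mL IGFBP1 stood above vehicle by 1.52 ± 0.18 (n = 3 against 3). Its libraries held 332.9 to 345.6 CPM at 500 and 282.6 to 361.2 at 20 µg/mL, against 106.2 to 130.4 in vehicle. The rise was thus present at the lowest dose and may include the part shared by all extracts. AKR1B10 (0.88 ± 0.07), GCLM (0.80 ± 0.07) and CYP1A1 (0.85 ± 0.11) rose as well. GNMT, a liver enzyme of methionine metabolism, fell by 0.99 ± 0.16 and GREB1L by 0.96 ± 0.12.

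Of 19 hypoxia targets 16 rose (adjusted p = 2.3e-25), such as KDM3A by 0.81 ± 0.08 and VEGFA by 0.54 ± 0.06, and NRF2 targets rose in 17 of 25, 18 adjusted over the list alone (1.4e-23). Heat shock genes rose in 7 of 15, 10 adjusted over the list alone (4.7e-12), and glycolysis genes in 11 of 17 (8.3e-12), with HK2 at 0.60 ± 0.07. Genes for DNA replication fell in 14 of 23, 15 adjusted over the list alone (8.1e-10), and AhR targets rose in 3 of 8 (0.00030). Cholesterol synthesis genes fell in 12 of 23 (6.7e-05, and adjusted p = 0.10 with an estimated correlation). Hypoxia, heat shock, glycolysis and replication genes had moved the same way at 20 µg/mL against vehicle. The test called 3346 genes (1747 higher, 1599 lower), and 1624 without extract replicate 2. Compared with the other extracts at 20 µg/mL it called 719, and 97 or 244 without extract replicate 2 or 3, with 394 called against both in the same direction.

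Between 20 and 500 µg/mL Rehmannia raised AKR1B10 by 1.23 ± 0.07, CYP1A1 by 1.07 ± 0.12 and ALDH3A1, an aldehyde dehydrogenase under AhR control, by 1.51 ± 0.21 (n = 3 against 3). KNG1, which encodes kininogen, fell by 0.68 ± 0.09. NRF2 targets rose in 18 of 25, 21 adjusted over the list alone (1.5e-94), and AhR targets in 3 of 8, 4 adjusted over the list alone (1.3e-13). Cholesterol synthesis genes fell in 3 of 23, 9 adjusted over the list alone (2.3e-08, and adjusted p = 0.037 with an estimated correlation). None of the 19 hypoxia targets was called by edgeR, over all genes or adjusted over the list alone, and the list's adjusted p was 0.013, with an adjusted p = 0.38 with an estimated correlation. The test called 235 genes (131 higher, 104 lower), and 24 without extract replicate 2 or 97 without extract replicate 3.

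Against vehicle at the lower doses of Rehmannia CA9 rose by 1.72 ± 0.20 at 100 µg/mL and IGFBP1 by 1.42 ± 0.18 at 20 µg/mL (n = 3 against 3). PTP4A3, a phosphatase, fell by 0.82 ± 0.12 at 100 µg/mL, and the pseudogene RPL7AP6 fell by 1.31 ± 0.21 at 20 µg/mL. AKR1B10 stood at 0.06 at 100 µg/mL and fell at 20 µg/mL (−0.35). The tests called 2362 genes at 100 µg/mL (1224 higher, 1138 lower, and 80 and 38 at a fold of at least 2) and 3313 at 20 µg/mL (1633 higher, 1680 lower). These counts were 553 and 797 without extract replicate 2, and 1297 and 1934 without vehicle replicate 2. Compared with the other extracts at 20 µg/mL 24 genes were called at 100 µg/mL, and 0 or 2 by edgeR without extract replicate 2 or 3. The dose of 20 µg/mL called 3, ZACN, ENSG00000219410 and ENSG00000259049, all higher and named after their values were seen, with 0, 0 and 7 without extract replicate 1, 2 and 3.

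Astragalus at 500 µg/mL changed more genes than any other extract and dose tested. AQP3, a channel for water and glycerol, rose by 4.94 ± 0.11, IGFBP1 by 4.80 ± 0.20, HCAR3, a receptor for hydroxylated fatty acids, by 4.15 ± 0.21 and CYP1A1 by 4.06 ± 0.10 (n = 3 against 3). FAM111B, a protease gene active in S phase, fell by 4.34 ± 0.12, and the sodium channel gene SCN1A (−4.29 ± 0.10), MT1G (−3.92 ± 0.21) and HAMP (−3.84 ± 0.20) also fell. Albumin, ALB, fell by 0.49 ± 0.07, and CDKN1A, an inhibitor of cell cycle kinases, rose by 1.41 ± 0.08.

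All 22 mitosis genes fell with Astragalus (adjusted p = 8.1e-21), among them TOP2A by 2.90 ± 0.11 and KIF11 by 2.58 ± 0.07, as did 22 of 23 genes for DNA replication (4.2e-22), with CDC6 at −1.97 ± 0.04 and UHRF1 at −2.61 ± 0.07. Autophagy and lysosome genes rose in 21 of 22 (3.7e-21), with the autophagy receptor SQSTM1 at 2.49 ± 0.06 and the lysosomal protease CTSB at 1.75 ± 0.04. TFEB, which encodes a transcription factor of lysosomal genes, fell (−0.32). The 14 immediate early genes rose (6.4e-15), with DUSP1 at 2.63 ± 0.07, as did all 17 glycolysis genes (2.3e-12), all 19 hypoxia targets (1.2e-10), 26 of 30 ATF4 targets (7.0e-10), 22 of 25 NRF2 targets (7.6e-10), 8 of 10 NF-kappaB targets (2.8e-05) and 7 of 8 AhR targets (0.0053). These calls held with an estimated correlation, and the counts of members in these directions were the same adjusted over the list alone.

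Some lists moved less evenly with Astragalus. Endoplasmic reticulum chaperones fell in 11 of 18 (0.036), such as HSPA5 (−1.13), and heat shock genes in 9 of 15 (0.017, and adjusted p = 0.18 with an estimated correlation), such as HSP90AA1 (−2.45), where both lists had risen at 20 µg/mL. Cholesterol synthesis genes rose in 16 of 23 (0.0025, and adjusted p = 0.21 with an estimated correlation), with DHCR7 at 1.22 but HMGCS1 at −0.31. Gluconeogenesis genes were called higher (0.014, and adjusted p = 0.065 with an estimated correlation) with a mean of 1.02 and a median of −0.01. Metallothioneins fell in 5 of 9 (0.014, and adjusted p = 0.25 with an estimated correlation). All 13 mitochondrially encoded genes rose (0.036, and adjusted p = 0.61 with an estimated correlation). The test called 11656 genes (5632 higher, 6024 lower). Versus the other extracts at 20 µg/mL it called 12687, and 10740 were called against both in the same direction.

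Within Astragalus the changes from 20 to 500 µg/mL were of the same order, with AQP3 at 4.76 ± 0.11, CYP1A1 at 4.00 ± 0.10 and RRAGD, a GTPase of lysosomal nutrient sensing, at 3.72 ± 0.27 (n = 3 against 3). KIF15, a mitotic kinesin, fell by 3.49 ± 0.13, as did MT1G (−4.26 ± 0.21). All 22 mitosis genes fell (3.8e-22), 21 of 22 autophagy and lysosome genes rose (3.5e-20) and heat shock genes fell in 11 of 15 (1.3e-05), calls that held with an estimated correlation. Hypoxia targets rose in 18 of 19 (1.8e-07, and adjusted p = 0.063 with an estimated correlation). The counts adjusted over the list alone were equal in these 4 lists. The test called 11607 genes (5710 higher, 5897 lower).

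At 100 µg/mL Astragalus raised IGFBP1 by 1.63 ± 0.18, the interleukin gene IL17B by 1.55 ± 0.14, CYP1A1 by 0.96 ± 0.11 and ASNS by 0.78 ± 0.05 (n = 3 against 3). IGFBP1 also lay above the vehicle libraries in all libraries of the other extracts at 100 µg/mL, so its rise may include the part shared by all extracts. GOLGA8B (−2.09 ± 0.13) and the collagen gene COL7A1 (−2.04 ± 0.17) fell most among named genes. Of the 651 genes with an annotated type that fell at least 2-fold, 369 (56.7%) were not protein-coding, against 21% of all genes tested, and with the other extracts at 20 µg/mL as reference it was 369 of 668 (55.2%). Among those that rose at least 2-fold it was 24 of 80 and, with the second reference, 24 of 64. At 20 µg/mL SOCS1, a feedback inhibitor of cytokine signalling, rose by 1.18 ± 0.11. The tests called 6595 genes at 100 µg/mL (3258 higher, 3337 lower) and 2198 at 20 µg/mL (1173 higher, 1025 lower). At a fold of at least 2 falls prevailed, with 81 higher and 659 lower at 100 µg/mL and 29 and 76 at 20 µg/mL. The latter count was 1178 without vehicle replicate 2, 628 without extract replicate 2 and 1265 without extract replicate 3. Versus the other extracts at 20 µg/mL 8125 genes were called at 100 µg/mL and 17 at 20 µg/mL, the latter being 2, 0 and 2 by edgeR without extract replicate 1, 2 and 3.

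In Cinnamon at 500 µg/mL HMGCS1 fell by 0.47 ± 0.05, LSS by 0.56 ± 0.06 and ACSS2, which makes acetyl-CoA for lipid synthesis, by 0.62 ± 0.05 (n = 3 against 3). The chaperones HSPA1A and HSPA8 rose by 1.12 ± 0.10 and 0.81 ± 0.05, as at 20 µg/mL. CYP1A1 rose by 0.50 ± 0.11, AKR1B10 by 0.40 ± 0.07 and PPP2R2C, a phosphatase subunit, by 0.98 ± 0.12. NEK8, a kinase of the cilium, fell by 0.80 ± 0.08.

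Genes of cholesterol synthesis fell in 17 of 23, 19 adjusted over the list alone (adjusted p = 7.5e-23), and fatty acid synthesis genes in 8 of 14 (5.5e-13). Heat shock genes rose in 10 of 15, 13 adjusted over the list alone (7.5e-23), hypoxia targets in 14 of 19 (8.8e-12), endoplasmic reticulum chaperones in 12 of 18, 14 adjusted over the list alone (4.2e-10), and NRF2 targets in 10 of 25, 13 adjusted over the list alone (3.0e-07). These 6 calls held with an estimated correlation. The test called 2448 genes (1316 higher, 1132 lower, and 36 and 75 at a fold of at least 2), and 667 without extract replicate 2, 1580 without vehicle replicate 2 or 1568 without vehicle replicate 3. Measured against the other extracts at 20 µg/mL it called 1804, and 623, 396 and 795 without extract replicate 1, 2 and 3, with 438 called against both in the same direction.

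Going from 20 to 500 µg/mL, Cinnamon lowered ACSS2 by 0.54 ± 0.05 and FADS2, a fatty acid desaturase, by 0.48 ± 0.05, and AKR1B10 rose by 0.66 ± 0.07 (n = 3 against 3). Of 23 cholesterol synthesis genes 15 fell, 22 adjusted over the list alone (6.7e-53), fatty acid synthesis genes in 5 of 14, 13 adjusted over the list alone (3.0e-37), and metallothioneins in 2 of 9, 8 adjusted over the list alone (8.8e-15). Of 25 NRF2 targets 9 rose, 15 adjusted over the list alone (3.9e-27). None of the 15 heat shock genes was called by edgeR, over all genes or adjusted over the list alone (list adjusted p = 0.0016, and adjusted p = 0.093 with an estimated correlation). CYP1A1 rose by 0.75 ± 0.11, a call that ended without extract replicate 2 (0.76, adjusted p = 0.069, the highest over all its alternatives). The test called 135 genes (44 higher, 91 lower), and 83, 4 and 21 without extract replicate 1, 2 and 3.

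At the lower doses of Cinnamon PFKFB3 stood above vehicle by 2.43 ± 0.21 at 100 µg/mL and 1.84 ± 0.22 at 20 µg/mL, and CA9 by 1.43 ± 0.20 at 100 µg/mL (n = 3 against 3). These rises cannot be credited to Cinnamon alone. Against the other extracts at 20 µg/mL PFKFB3 stood at 0.58 ± 0.13 (adjusted p = 0.011) and −0.01 ± 0.14 (not called), and CA9 at 0.39 ± 0.14 at 100 µg/mL (not called). PPARGC1B, a coactivator of mitochondrial genes, fell by 0.89 ± 0.12 at 20 µg/mL. CYP1A1 stood at −0.29 and −0.26, neither called. The tests called 1316 genes at 100 µg/mL (696 higher, 620 lower) and 1805 at 20 µg/mL (958 higher, 847 lower). The count at 100 µg/mL was 2422, 199 and 541 without extract replicate 1, 2 and 3, and 736 and 815 without vehicle replicate 2 and 3. The count at 20 µg/mL was 402 and 915 without extract replicate 2 and 3, and 977 without vehicle replicate 2. Measured against the other extracts at 20 µg/mL 807 genes were called at 100 µg/mL, but 2 without the Cinnamon library of replicate 1 alone, a run chosen after seeing the data (742 and 899 without that of replicate 2 or 3 alone), and 22, 15 and 668 without replicate 1, 2 and 3 of all extracts. At 20 µg/mL 0 were called by edgeR, where 1563 had an unadjusted p below 0.05, and 1 without extract replicate 1.

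Sagunja-tang at 500 µg/mL raised CYP1A1 by 5.05 ± 0.11 (n = 2 against 3), to 389.2 ± 13.6 CPM (SD). ALDH3A1 rose by 2.22 ± 0.20, AKR1B10 by 2.20 ± 0.07 and UGT1A1, which conjugates bilirubin and drugs, by 1.76 ± 0.09. AQP3 rose by 1.78 ± 0.14 and NQO1, a quinone reductase shared by the AhR and NRF2 lists, by 1.25 ± 0.07. GNMT fell by 1.87 ± 0.20, MT1F by 1.75 ± 0.18 and the tight junction gene TJP3 by 1.68 ± 0.15.

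NRF2 targets rose in 21 of 25, 22 adjusted over the list alone (adjusted p = 3.6e-58), AhR targets in 6 of 8 (2.7e-28) and ATF4 targets in 15 of 30, 16 adjusted over the list alone (6.8e-10), with SLC7A11 at 1.36 ± 0.08 and ASNS at 0.80 ± 0.06. PXR and CAR targets rose in 4 of 8 (1.8e-07). Cholesterol synthesis genes fell in 17 of 23, 18 adjusted over the list alone (9.2e-17), with HMGCS1 at −0.66 ± 0.06. Metallothioneins fell in 6 of 9 (1.9e-06) and genes of proteins that hepatocytes secrete in 10 of 20 (4.8e-05), with ALB at −0.41 ± 0.08 and hemopexin, HPX, at −1.04. Hypoxia targets rose in 7 of 19, 9 adjusted over the list alone (9.1e-05, and adjusted p = 0.17 with an estimated correlation). The test called 4276 genes (2309 higher, 1967 lower, and 98 and 244 at a fold of at least 2), and 1490 without extract replicate 2, when ALB (−0.41) was no longer called with an adjusted p of 0.059, the highest over its alternatives. From the other extracts at 20 µg/mL it differed in 3816, and 2297 or 1376 without extract replicate 1 or 2, with 2173 called against both in the same direction.

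Across the step from 20 to 500 µg/mL the formula raised CYP1A1 by 4.81 ± 0.13, ALDH3A1 by 2.49 ± 0.23 and AKR1B10 by 2.31 ± 0.09 (n = 2 against 2), and lowered MT1F by 1.89 ± 0.18 and KNG1 by 1.26 ± 0.11. AhR targets rose in 7 of 8 (1.1e-39) and NRF2 targets in 20 of 25, 22 adjusted over the list alone (1.1e-89). Of 23 genes of cholesterol synthesis 20 fell (5.6e-27), metallothioneins in 7 of 9 (1.9e-12) and secreted hepatocyte proteins in 10 of 20, 12 adjusted over the list alone (7.2e-11). All 5 calls held with an estimated correlation. The test called 1741 genes (951 higher, 790 lower, and 57 and 65 at a fold of at least 2), and 756 without extract replicate 1 or 260 without extract replicate 2.

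At 100 µg/mL Sagunja-tang raised CYP1A1 by 1.90 ± 0.11 against vehicle and NQO1 by 0.25 ± 0.07 (n = 2 against 3), and at 20 µg/mL CYP1A1 stood at 0.24 ± 0.12, not called. PTP4A3 fell by 1.14 ± 0.14 and 1.03 ± 0.14 at these doses, and PPP2R2C rose by 1.24 ± 0.13 at 20 µg/mL. The tests called 2416 genes at 100 µg/mL (1229 higher, 1187 lower) and 2184 at 20 µg/mL (1068 higher, 1116 lower, and 36 and 78 at a fold of at least 2). Without extract replicate 1 these counts were 1520 and 1412, without extract replicate 2 they were 216 and 68, and without vehicle replicate 2 they were 1410 and 1021. From the other extracts at 20 µg/mL 142 genes differed at 100 µg/mL, and 25 or 6 without extract replicate 1 or 2, and 0 at 20 µg/mL by edgeR, where 444 had an unadjusted p below 0.05.

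Direct comparisons at 500 µg/mL asked where 2 extracts differ without use of vehicle. Angelica exceeded Paeonia in MT1G by 2.72 ± 0.23, GSTA2 by 2.37 ± 0.13 and CYP1A1 by 0.78 ± 0.11 (n = 2 against 2), and was below it in IGFBP3 (−3.70 ± 0.22), IGFBP1 (−3.52 ± 0.23) and the FOXO target DEPP1 (−3.12 ± 0.19). The amino acid enzyme ASNS (−1.38 ± 0.07) was also lower in Angelica. The test called 6535 genes (3138 higher in Angelica, 3397 lower), and 3380 without extract replicate 2 or 4286 without extract replicate 3.

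Cnidium exceeded Rehmannia in AKR1B10 by 2.18 ± 0.07, PTGR1 by 1.95 ± 0.06 and NQO1 by 0.69 ± 0.06 (n = 3 against 3). CYP1A1 (−0.69 ± 0.11), CA9 (−1.41 ± 0.20) and DEPP1 (−1.42 ± 0.16) were lower in Cnidium. The test called 1678 genes (794 higher, 884 lower, and 24 and 52 at a fold of at least 2), and 1047, 525 and 862 without extract replicate 1, 2 and 3. Angelica and Cnidium, both of the carrot family, differed in CYP1A1, higher in Angelica by 2.88 ± 0.11, and BMF, higher by 1.34 ± 0.10 (n = 2 against 3). AKR1B10 (−1.98 ± 0.08), PTGR1 (−1.70 ± 0.07) and SLC5A11 (−1.63 ± 0.21) were lower in Angelica. These 2 extracts carry different code prefixes, unlike the pairs of the other direct comparisons, although all titles share a batch label. Whatever a prefix stands for and the extract cannot be told apart in this contrast. The test called 1360 genes (647 higher in Angelica, 713 lower), and 230 without extract replicate 2 or 429 without extract replicate 3.

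Astragalus exceeded Cinnamon in AQP3 by 4.54 ± 0.11, IGFBP1 by 4.18 ± 0.19 and the interleukin receptor IL21R by 3.98 ± 0.22 (n = 3 against 3). FAM111B (−4.22 ± 0.12), the kinetochore motor CENPE (−3.63 ± 0.22) and HAMP (−3.58 ± 0.21) were lower in Astragalus. The test called 11746 genes (5817 higher in Astragalus, 5929 lower).

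Samul-tang, a formula made as background knowledge from the Angelica, Paeonia, Cnidium and Rehmannia drugs, had 1 library per dose, so no dose was tested alone and its values per dose have no replicate. With the 3 doses as a group against vehicle (n = 3 against 3, own fit), CYP1A1 rose by 2.08 ± 0.34 (adjusted p = 0.0018) and stood at 2.87, 1.83 and 1.01 in the libraries of 500, 100 and 20 µg/mL. PFKFB3 rose by 1.51 ± 0.14, CA9 by 1.02 ± 0.19 and TMCC1 by 1.14 ± 0.08, and RN7SL1 fell by 2.00 ± 0.20. GNMT fell by 0.94 ± 0.14 and PTP4A3 by 0.83 ± 0.09, while AKR1B10 stood at 1.47, 0.37 and −0.02 in the 3 libraries and was not called. The spread of these 3 libraries includes any change with dose, so genes that grade with dose are harder to call in this test. Hypoxia targets rose in 13 of 18 and genes for DNA replication fell in 14 of 23, 14 and 16 adjusted over the list alone. Both lists, and PFKFB3, CA9, TMCC1 and RN7SL1, had moved the same way in the replicated extracts at 20 µg/mL against vehicle. Samul-tang was tested against vehicle only, so its changes and its count of called genes may include this shared part. NRF2 targets rose in 6 of 25, 10 adjusted over the list alone. The test called 2652 genes (1422 higher, 1230 lower, and 34 and 61 at a fold of at least 2), and 1407 without vehicle replicate 2 or 1409 without the library of 100 µg/mL.

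Similarity between extracts was described by the correlation across genes of the log2 change from 20 to 500 µg/mL, in which genes are not independent replicates and no p was computed. Over 16692 genes Paeonia and Astragalus had a Pearson correlation of 0.40 and a Spearman correlation of 0.51, and between single replicate pairs the former ran from 0.39 to 0.45. The other 20 pairs of the 7 replicated extracts had Pearson correlations of −0.03 to 0.22, the highest for Cnidium and Sagunja-tang, which had 0.43 by Spearman correlation. The ranking depended on the measure. Over genes called in either extract Paeonia and Astragalus had 0.56, below Cnidium and Cinnamon (0.60), Angelica and Cinnamon (0.59) and Angelica and Cnidium (0.58). These values rest on 12300, 3077, 241 and 3080 genes in that order, so they do not compare like sets of genes. Samul-tang, with single libraries, had Pearson correlations of 0.03 with Angelica, 0.05 with Paeonia, 0.09 with Cnidium and 0.06 with Rehmannia, its drugs, and 0.01 with Astragalus, 0.06 with Cinnamon and 0.09 with Sagunja-tang. Over the genes called in the other extract these were 0.49, 0.10, 0.50 and 0.51 for its drugs, and −0.01, 0.84 and 0.64, where 135 genes were called for Cinnamon, so the low values over all genes do not show a lack of resemblance. Altogether 28 such pairs were computed.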

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

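The tests on code prefixes, on scaling in Astragalus and on its 100 µg/mL dose were chosen only after the result was seen. Differences between extracts at 500 µg/mL, each tested directly, are given here because they separate groups under the same contrast. Angelica and Paeonia differed in 6535 genes, with CYP1A1 at 0.78, ASNS at −1.38, CDKN1A at −1.03 and ALB at −0.22. Without extract replicate 2 or 3 they differed in 3380 and 4286 genes. Cnidium and Rehmannia differed in 1678 genes, with CYP1A1 at −0.69, NQO1 at 0.69, HMOX1 at 0.54, ASNS at 0.49 and CDKN1A at −0.25, and in 1047, 525 and 862 without extract replicate 1, 2 and 3. Astragalus and Cinnamon differed in 11746 genes, with CYP1A1 at 3.56, NQO1 at 0.70, HMOX1 at 0.85, ASNS at 1.53, CDKN1A at 1.52 and ALB at −0.43. Angelica and Cnidium differed in 1360 genes, with CYP1A1 at 2.88, NQO1 at −0.75, HMOX1 at −0.60 and ASNS at −0.73, and in 230 and 429 without extract replicate 2 and 3, and as their code prefixes differ a batch may have a part in this.

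Genes such as PFKFB3, TMCC1 and HSPA8 differed from vehicle at 20 µg/mL in all 7 replicated extracts, 778 genes in the same direction in each. GC content or transcript length is argued against as the whole cause, since 693 of them were still called in all 7 after correction. Among simulated groups with no effect set against shared vehicle libraries 0 such genes arose. That simulation drew each gene independently, so a shift of the vehicle libraries across many genes could not arise in it. It therefore cannot decide on chance from the shared vehicle libraries. An action that grows with dose is argued against by the median signed change from 20 to 500 µg/mL of genes chosen in 4 other extracts, −0.03 in Cinnamon and −0.05 in Sagunja-tang. Vehicle libraries made or cultured apart from the extract libraries stay open, as vehicle and extracts shared 0 code prefixes. The titles of all libraries carry the same batch label, BatchD, but titles and codes do not say what that label or a prefix covers. Handling by prefix and treatment therefore cannot be told apart. An action common to the extracts that is complete at 20 µg/mL, and the DMSO content the sources dispute, were not tested and may account for it as well.

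The response to Astragalus at 500 µg/mL, with mitosis genes such as TOP2A lower and lysosomal genes such as CTSB higher, was weighed next. Scaling between libraries cannot make the gap between the autophagy and lysosome list and the mitosis list, because 1 factor per library moves both alike. Their median changes lay 2.47 apart. The test was chosen after these moves were seen, and the gap cannot tell how far scaling shifts the count of genes called. GC content or transcript length is argued against for the fall of mitosis and replication genes, of which 44 of 45 were lower before and 44 after correction, although the changes of all genes did follow GC content (Spearman correlation 0.39). In libraries not used to choose them, the 3831 genes changed at least 2-fold from 20 to 500 µg/mL had a median signed change in Astragalus at 100 µg/mL that lay 0.38 above that in Cinnamon at 100 µg/mL, consistent with a graded response to the Astragalus extract. Cell growth and viability were not analysed here.

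Paeonia and Astragalus changed in similar ways from 20 to 500 µg/mL, in IGFBP1, IGFBP3, HAMP, MT1G and the mitosis genes among others, with a Pearson correlation of 0.40. Neither GC content or transcript length (0.41 after correction) nor a few genes with large changes (0.33 over 11990 genes below 2-fold in both) is likely to be the whole cause. A dose change common to all extracts was set against the highest other pair, at 0.22, and the distance met the bound written beforehand. That bound was too weak, because by Spearman the values were 0.51 and 0.43 and over called genes 0.56 and 0.60. The last 2 values rest on unlike sets, of 12300 and 3077 genes. A common part stays open. Shared constituents or a shared stress response, such as through growth inhibition, were not tested.

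Other splits of 3 libraries against 3 were fitted on the libraries of each comparison, and 10 splits are too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes. Every other split mixes libraries of both groups, so a difference between the groups widens the spread on both sides and keeps its count low. Low counts of the other splits are therefore no support for the real one. The real count and the highest of the others were 10477 and 0 for Astragalus at 500 µg/mL against vehicle, 6567 and 0 at 100, 3030 and 1 at 20, 10508 and 0 from 20 to 500, and 10469 and 0 against Cinnamon. They were 2515 and 1 for Cinnamon at 500 µg/mL, 403 and 1 at 100, 2086 and 1 at 20, and 30 and 4 from 20 to 500. For Cnidium they were 5515 and 0 at 500 µg/mL, 3629 and 1 at 100, 3657 and 3 at 20, 3206 and 1 from 20 to 500, and 1643 and 1 against Rehmannia. Rehmannia gave 3878 and 0 at 500 µg/mL, 3515 and 0 at 100, 1865 and 1 at 20, and 17 and 3 from 20 to 500. Samul-tang gave 2652 and 1.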

How the results depend on the processing

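The offset for GC content and length, and the other extracts' 20 µg/mL groups as reference for the 2 lower doses, were chosen after seeing the data, as was leaving out single Cinnamon libraries at 100 µg/mL. RLE factors kept all 33 counts of genes within 1.5 times, as did the replicate block (32) and the block within code prefix (10). DESeq2 kept 32 of 33, the GC and length offset 30 of 32, no filter 30 of 33 and the fit of 2 groups 25 of 32. Where a count moved, the cause was not tested, except that a fold limit lowers counts by construction. Leaving a replicate out of a group of 2 leaves 1 library, assumed to vary like the other groups. Over 413 named pairs of gene and comparison, 3571 of 3727 values under alternatives kept direction and side of the threshold, 134 lost the call, 13 gained it and 9 changed sign. How far depth limits genes with low counts, such as CYP3A4, was not tested.

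With a fold of at least 2 the counts at 500, 100 and 20 µg/mL against vehicle were 208, 193 and 214 for Angelica, 1064, 165 and 155 for Paeonia, 357, 132 and 111 for Cnidium, 167, 118 and 128 for Rehmannia, 3955, 740 and 105 for Astragalus, 111, 71 and 80 for Cinnamon and 342, 139 and 114 for Sagunja-tang. Of these 97, 80 and 100, 592, 84 and 72, 106, 57 and 53, 88, 80 and 71, 1600, 81 and 29, 36, 40 and 33, and 98, 56 and 36 were higher, in the same order. From 20 to 500 µg/mL they were 7 for Angelica, 596 for Paeonia, 158 for Cnidium, 9 for Rehmannia, 3831 for Astragalus, 3 for Cinnamon and 122 for Sagunja-tang, with 5, 347, 57, 5, 1630, 0 and 57 higher. Between extracts they were 813 for Angelica and Paeonia, 76 for Cnidium and Rehmannia, 4114 for Astragalus and Cinnamon and 73 for Angelica and Cnidium, and 95 for Samul-tang, with 305, 24, 1757, 43 and 34 higher.

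Against the other extracts at 20 µg/mL, moved counts were 1047 at 500, 22 at 100 and 1 at 20 µg/mL for Angelica, 45 at 100 and 1 at 20 µg/mL for Paeonia, 355 at 100 and 1 at 20 µg/mL for Cnidium, 719 at 500, 24 at 100 and 3 at 20 µg/mL for Rehmannia, 17 at 20 µg/mL for Astragalus, 807 at 100 and 0 at 20 µg/mL for Cinnamon and 142 at 100 and 0 at 20 µg/mL for Sagunja-tang, where the reference itself differs. By edgeR 1563 genes of Cinnamon and 444 of Sagunja-tang had an unadjusted p below 0.05 at 20 µg/mL. From 20 to 500 µg/mL Angelica had 269 genes by DESeq2, 278 with the GC and length offset, 388 with no filter and 46 in a fit of 2 groups. Cinnamon had 203 with the offset, 210 with no filter and 30 in a fit of 2 groups, and Rehmannia 432 and 17 in the latter pair. Against vehicle the fit of 2 groups gave 1865 for Rehmannia at 20, 403 for Cinnamon at 100, 3638 for Sagunja-tang at 100 and 3334 at 20 µg/mL.

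With an estimated correlation camera called 9 lists in place of 14 for Angelica, 8 of 21 for Cnidium and 6 of 11 for Cinnamon at 500 µg/mL against vehicle, and from 20 to 500 µg/mL 6 of 17 for Angelica, 5 of 16 for Rehmannia and 7 of 14 for Cinnamon. It kept 137 of 224 calls and fry kept 208. Fry called 27 lists for Paeonia and 31 for Astragalus against vehicle, and 11 for Angelica and 29 for Astragalus from 20 to 500 µg/mL. By Spearman correlation Samul-tang had 0.14 with Angelica, 0.07 with Paeonia, 0.26 with Cnidium, 0.18 with Rehmannia, −0.03 with Astragalus, 0.17 with Cinnamon and 0.26 with Sagunja-tang, and Paeonia and Astragalus had 0.51. Over genes called in the other extract, as it had no test of its own from 20 to 500 µg/mL, Samul-tang had 0.49 with Angelica, 0.10 with Paeonia, 0.50 with Cnidium, 0.51 with Rehmannia, −0.01 with Astragalus, 0.84 with Cinnamon and 0.64 with Sagunja-tang, and over genes called in either extract Paeonia and Astragalus had 0.56.

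Leaving out replicates, vehicle replicate 1 moved 0 of 22 edgeR counts by over 1.5 times, vehicle replicate 2 moved 13, vehicle replicate 3 moved 2, and extract replicates 1, 2 and 3 moved 6 of 23, 27 of 32 and 14 of 28. An extract replicate number was removed from all replicated extracts that have it at once. Number 2 is the only one found in every replicated extract, so leaving it out removed the most libraries. These values therefore cannot tell whether replicate 2 stood apart or the loss of libraries lowered the counts. Counts against vehicle at 500, 100 and 20 µg/mL ran from 914 to 3114, 849 to 2976 and 1243 to 4117 for Angelica, from 5203 to 7281, 173 to 2650 and 114 to 2927 for Paeonia, from 3023 to 4647, 832 to 2599 and 1511 to 2369 for Cnidium, from 1624 to 2826, 553 to 2091 and 797 to 3862 for Rehmannia, from 10785 to 11326, 5087 to 5932 and 628 to 2094 for Astragalus, from 667 to 2438, 199 to 2422 and 402 to 2093 for Cinnamon and from 1490 to 3848, 216 to 2006 and 68 to 1758 for Sagunja-tang. From 20 to 500 µg/mL they ran from 9 to 24 for Angelica, 2339 to 2698 for Paeonia, 1318 to 2311 for Cnidium, 24 to 157 for Rehmannia, 10196 to 10827 for Astragalus, 4 to 83 for Cinnamon and 260 to 756 for Sagunja-tang. Between extracts they ran from 3380 to 4286 for Angelica and Paeonia, 525 to 1047 for Cnidium and Rehmannia, 10288 to 11012 for Astragalus and Cinnamon and 230 to 1620 for Angelica and Cnidium, and from 1407 to 2384 for Samul-tang, whose count without the 100 µg/mL library was 1409.

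The values that changed sign belong to CYP3A4 and ALB at 500 µg/mL and were not called in any setting. Over the replicates left out, CYP3A4 ran from −0.06 to 1.22 in Angelica, −0.50 to 0.89 in Paeonia, −0.53 to 0.75 in Rehmannia and −0.28 to 0.99 in Cinnamon, CYP3A4 in Cnidium 500 versus vehicle from −0.95 to 0.33, and ALB in Paeonia from −0.04 to 0.01. CYP3A4 changed sign in Rehmannia (0.37 without extract replicate 1 and 0.75 without vehicle replicate 1), in Cnidium (0.33 without vehicle replicate 1), in Paeonia (−0.50 without extract replicate 3 and −0.38 without vehicle replicate 2), and without the latter in Angelica (−0.06) and Cinnamon (−0.28). ALB in Paeonia stood at 0.00 without extract replicate 2 and 0.01 without vehicle replicate 3. The cause was not tested.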

Other observations

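From 20 to 500 µg/mL CYP7A1, the enzyme that starts bile acid synthesis, fell by 1.11 ± 0.16 in Paeonia, by 0.55 ± 0.12 in Cnidium, by 1.07 ± 0.13 in Astragalus and by 0.56 ± 0.15 in Sagunja-tang, and AKR1D1, a later enzyme of the pathway, changed by −0.71 ± 0.08, −0.34 ± 0.06, −1.79 ± 0.07 and −0.57 ± 0.07 in the same order. NR1H4, the bile acid receptor FXR, fell by 0.88 ± 0.07 in Paeonia and by 0.52 ± 0.07 in Sagunja-tang, also fell in Astragalus, and was not called in Cnidium (0.10). NR0B2, a repressor induced by that receptor, rose by 0.45 ± 0.08 in Paeonia and 1.46 ± 0.07 in Astragalus and fell by 0.36 ± 0.07 in Cnidium. The bile acid list as a whole was called lower in Sagunja-tang, where 5 of 11 genes fell, 6 adjusted over the list alone (camera adjusted p = 1.1e-05, and adjusted p = 0.002 with an estimated correlation). It was called lower in Cnidium, Rehmannia and Cinnamon with the preset (0.032, 0.013 and 0.026) but not with an estimated correlation (0.12, 0.10 and 0.14), and in Angelica, Paeonia and Astragalus with neither. These genes were chosen after their values were seen, from lists fixed beforehand.

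FTH1, a subunit of the iron store ferritin, rose from 20 to 500 µg/mL by 0.75 ± 0.07 in Cnidium, 0.39 ± 0.07 in Rehmannia, 1.40 ± 0.08 in Astragalus, 0.38 ± 0.09 in Paeonia and 0.37 ± 0.09 in Sagunja-tang. FTL, the other subunit, rose in the first 4 of these, by 0.75 ± 0.10, 0.52 ± 0.10, 1.14 ± 0.10 and 0.34 ± 0.13, and in Angelica by 0.48 ± 0.13, and was not called in Sagunja-tang (0.35 ± 0.13). HAMP fell by 2.92 ± 0.22 in Astragalus and by 2.53 ± 0.32 in Paeonia and was not called in Cnidium (−0.07 ± 0.14), Rehmannia (0.10 ± 0.15), Sagunja-tang (0.11 ± 0.17) or Angelica (−0.06 ± 0.17). The export gene SLC40A1 rose by 0.47 ± 0.06 in Astragalus and fell by 0.29 ± 0.08 in Sagunja-tang. The difference between extracts was not tested for these genes from 20 to 500 µg/mL.

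Cinnamon replicate 1 at 100 µg/mL resembled vehicle on the second principal component (25.9), yet its PFKFB3 stood at 11.4 CPM where vehicle ran from 1.83 to 2.78. A score was formed as the mean log2 CPM of the 449 genes higher in all 7 extracts at 20 µg/mL minus that of the 329 lower ones, relative to vehicle. It was 0.38 in that library, against 0.76 and 0.78 in the others of its group and −0.07 to 0.04 in vehicle. Over the 57 extract libraries it ran from 0.34 to 1.04. Its genes were chosen by their difference from these same vehicle libraries, so a gap between vehicle and the rest follows from that choice. The score therefore cannot tell whether that Cinnamon library was treated as labelled.

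Of the genes with an annotated type that fell at least 2-fold against vehicle at 500 µg/mL, 44.7% were not protein-coding in Paeonia (210 of 470), 32.9% in Astragalus (767 of 2329), 44% in Sagunja-tang (107 of 243) and 39.2% in Cnidium (98 of 250), against 21% of all genes tested. With the other extracts at 20 µg/mL as reference the shares were 35% (97 of 277), 32.2% (785 of 2438), 33.8% (45 of 133) and 30.8% (37 of 120). Among rises of at least 2-fold against vehicle 115 of 587, 241 of 1598, 24 of 98 and 30 of 106 were not protein-coding, in the same order. Against the other extracts they were 83 of 440, 299 of 1773, 17 of 78 and 43 of 106. In Cnidium the excess over 21% was thus found among rises too. CYP3A4, a drug-metabolising enzyme, was low in vehicle, at 0.208 ± 0.167 CPM (SD, n = 3), and was called in none of the 7 extracts at 500 µg/mL by edgeR, although it was called in Astragalus at 100 µg/mL (1.15, adjusted p = 0.036). In single libraries of Samul-tang, 18 of 10473 genes with at least 5 CPM lay at least 2-fold above the vehicle mean at 500 µg/mL and 8 below, against 11 and 5 at 20 µg/mL.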
